A study of Mus musculus with 12 samples.

How the data were processed

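The series comprises 12 libraries from hearts of 11-week-old mice, of which 6 were analysed here. These are total RNA libraries of 3 control and 3 knockout samples, made with the TruSeq protocol with random hexamer priming after Ribo-Zero removal of rRNA, per the labels' protocols. The other 6 libraries, made from mitochondrial RNA by parallel analysis of RNA ends (PARE), were not analysed here. Groups were taken from the source names and genotypes in the labels, and replicate numbers from the source names. The labels number the samples of a group as replicates but do not say outright that each came from its own animal, so p-values measure the spread between these samples. The Cre transgene is carried only by the knockouts, so an effect of Cre cannot be separated from that of the gene.

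The deposited values are FPKM (fragments scaled to transcript length and to mapped fragments) for each locus and library, per the file names and headers, and each file holds 1 library. Per the submitters' processing notes, the tools named for these libraries include HISAT 0.1.6, StringTie 1.1.0, Cufflinks 2.2.1, Cuffdiff, HISAT2 2.0.1, SAMtools 1.3, Picard 1.23 and bedtools, with the builds GRCm38 and mm10. Their roles, order and settings, the gene annotation, any scaling between libraries and any use of strand are not given in the sources used here. Each file lists 44450 loci. Of these, 950 carry more than 1 gene name, so overlapping genes share a value, and 21947 are at 0 in every library. Of the 45742 gene names listed, 32318 were found as current symbols in the RefSeq gene table of assembly GRCm38.p6, which was used for biotypes, positions and the symbol Prorp (listed in the files as 1110008L16Rik). FPKM are not counts, so no count model was used. A value of exactly 0 can be a failed estimate: 4 loci, mt-Rnr1, mt-Co1, the merged mt-Atp6, mt-Atp8 and mt-Co3 locus, and Ttn, were at 0 in some libraries and very abundant in others. For these only listed values are given.

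Depth is not stated in the files. For pseudogene and small RNA loci under 1 FPKM in every library, the most frequent ratio of values between 2 libraries was taken as the ratio of what 1 fragment is worth. It was read from 321 to 371 loci per pair, of which 65 to 88 lay at the most frequent ratio. Whole read numbers could not be recovered, so no counting interval is given.

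Values were analysed as log2(FPKM + 0.5) without further scaling, over 12181 loci with at least 1 FPKM in at least 3 of the 6 libraries. Knockout was compared with control by limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. Folds are on this log2 scale. Before the data were examined, 44 gene lists with 880 members were fixed, of which 8 members (Cox4i1, Slc7a5, Afg3l1, Spg7, Acta1, Map1lc3b, Dpep1 and Tubb3) were not analysed here. The 39 lists with at least 4 measured loci were tested with camera, which compares a list with all other loci, at a preset inter-gene correlation of 0.01, and Benjamini-Hochberg adjusted over lists. With a correlation estimated from the data none of the 24 camera calls held. The smallest adjusted p was then 0.45, and 1 list had an unadjusted p under 0.05. Fry, which asks whether the members of a list move in 1 direction on balance without comparing them with other genes, passed for 13 lists. Members were also counted with adjustment over all loci and over the list alone. The mtDNA-encoded share of summed FPKM was compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 is 0.10.

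The genes named were set by a rule fixed before the data were examined. It takes Prorp and the other RNase P list members, and the mtDNA-encoded mRNAs and rRNAs. It also takes the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with non-overlapping groups and a mean of at least 2 FPKM in the higher group. From each list it takes up to 4 members past the threshold with the largest change, or the 2 most abundant members where none passed. The 4 loci with listed zeros were left out of the largest changes, a choice made after the values were seen. Members that went against the direction of their list, and Myl7, Hbb-bs and Ttn, were named after their values were seen. Of the list members the rule takes, the text prints examples, mostly ones whose call held with each library left out, chosen after the values were seen. The others are not reported here.

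The fit was tested on simulated libraries with the means and spreads of these 12181 loci. For knockout against control, 59% of 100 loci changed 2-fold and 92% of 100 loci changed 4-fold were recovered, 7.36% of calls were unchanged loci, and camera called 2 of 2 planted and 0 of 40 unchanged lists. The simulated loci vary independently, so this does not test lists whose members vary together. Only those loci were changed, far fewer than the 4343 called in the data, so the recovery rates need not carry over. Each planted list held only changed loci that moved in 1 direction, an easy case. No pair of libraries was identical. Alternatives were other pseudocounts (0.1 and 1), no filter, a mean of at least 5 FPKM, 4 scalings (mtDNA-encoded loci removed and the rest scaled to one sum, median-of-ratios, quantile, and a sum of 1000000), 3 variance models, the replicate number as a block, and each library left out. An alternative without the 4 loci with listed zeros, and the share over mtDNA-encoded loci above 0 in every library, were added after seeing the data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the plots.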

Results

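Hearts of 11-week-old C57BL/6N mice were profiled by total RNA sequencing, with 3 libraries from control mice homozygous for a loxP-flanked Mrpp3 gene and 3 from knockout mice that also carried a Cre transgene driven by the muscle creatine kinase promoter (Ckmm). MRPP3, encoded by the gene now called Prorp, is the nuclease subunit of mitochondrial RNase P, which cuts the 5′ ends of tRNAs out of the long transcripts of mitochondrial DNA. The comparison asks how the heart transcriptome differs when this enzyme is removed from muscle. Each library gave an FPKM value for 44450 loci, and 12181 loci with at least 1 FPKM in at least 3 of the 6 libraries were tested. The files give no read totals. The steps between the lowest values placed the depth of the other control libraries at 1.32 and 1.35 times that of control replicate 1, and the depth of the knockout libraries at 2.57, 2.06 and 2.19 times (replicates 1 to 3). Between 11753 and 12272 loci reached 1 FPKM in each library, so the knockout libraries were deeper but did not hold many more loci at this level. Loci above 0 numbered 17925 to 18330 in controls and 19246 to 19667 in knockouts. Depth thus differed with genotype, and zeros are less certain in the controls. A further 6 libraries of mitochondrial RNA cut sites (PARE) were not analysed here. Values below are mean FPKM ± SD over 3 libraries, and log2 fold changes are knockout over control on the log2(FPKM + 0.5) scale, which understates changes of low genes.

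Prorp RNA was low in every library labelled knockout. It stood at 3.49, 2.64 and 3.23 FPKM in the controls and at 0.441, 0.701 and 0.555 FPKM in the knockouts, a log2 fold change of -1.77 (SE 0.17, limma adjusted p = 0.00063). The gene, listed in the files as 1110008L16Rik (locus XLOC_007949), spans 55302637 to 55382492 on chromosome 12 of GRCm38, and the labels used here do not say which of its exons the loxP sites flank. Among the 5 fixed members of the RNase P and tRNA end-processing list, 2 rose and 1, Prorp itself, fell, and the same number passed when adjusted over the list alone. Trnt1, which adds the CCA tail to tRNAs, rose from 10.8 ± 0.512 to 21.8 ± 5.71 FPKM (log2 fold change 0.95, SE 0.19, limma adjusted p = 0.0083). Elac2, the nuclease for tRNA 3′ ends, rose from 6.82 ± 0.746 to 11.8 ± 2.75 FPKM (limma adjusted p = 0.021), a call lost without any one of the controls or knockout replicate 1 (adjusted p = 0.077, 0.055, 0.054 and 0.064). The other 2 subunits of mitochondrial RNase P did not pass the test. Hsd17b10 had 80.2 ± 1.70 FPKM in controls and 55.8 ± 21.2 in knockouts (log2 fold change -0.60, limma adjusted p = 0.13). It passed with array weights (adjusted p = 0.021) and without knockout replicate 3 (log2 fold change -0.85, adjusted p = 0.030), and stood at -0.27 without knockout replicate 2. Trmt10c had 7.28 ± 0.403 and 5.60 ± 1.40 (limma adjusted p = 0.15). The list as a whole did not pass camera (adjusted p = 0.82, or 0.91 with an estimated correlation).

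Of the transcripts encoded by mitochondrial DNA, mt-Cytb, which encodes the cytochrome b subunit of complex III, was far lower in the knockout. It fell from 17466 ± 1582 to 3655 ± 837 FPKM (log2 fold change -2.28, SE 0.35, limma adjusted p = 0.0032), with every knockout library below every control. mt-Cytb lies at 14145 to 15288 of the mitochondrial genome (GRCm38), the last protein gene along its heavy-strand transcript. The complex I loci mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5 and mt-Nd6 did not pass the test. FPKM of a locus count fragments of cut and uncut transcripts alike, so these values do not show whether mature mRNAs were spared. The locus mt-Nd2,mt-Tw had 10873 ± 1294 FPKM in controls and 12573 ± 4556 in knockouts (log2 fold change 0.14, SE 0.43, limma adjusted p = 0.82), a difference that turned to -0.09 without knockout replicate 3. The locus mt-Nd4,mt-Nd4l had 4468 ± 562 and 4865 ± 1143 FPKM (log2 fold change 0.10, SE 0.32, limma adjusted p = 0.83), a difference that was below 0 without control replicate 3 turned to -0.03 without knockout replicate 1 and was 0.69 after quantile normalization (adjusted p = 0.094). mt-Nd5 had 3847 ± 351 and 3336 ± 682 FPKM, with a log2 fold change of -0.22 (limma adjusted p = 0.57) that turned to 0.42 after quantile normalization and to 0.01 after scaling each library to one sum. The remaining loci with a value in every library were mt-Nd1 (25193 ± 1727 and 15128 ± 4787 FPKM, log2 fold change -0.79, SE 0.46, limma adjusted p = 0.22), mt-Co2 (307 ± 14.9 and 231 ± 85.2), mt-Nd6 (417 ± 105 and 285 ± 26.0) and mt-Nd3 (33.0 ± 0.688 and 23.5 ± 4.79). Only mt-Nd3 of these passed, at a limma adjusted p of 0.047 that rose to between 0.053 and 0.13 without any one library except knockout replicate 1. This call was also lost scaled to a sum of 1000000 (log2 fold change -0.27, against -0.50, adjusted p = 0.21), with no filter (0.074), with the replicate block (0.076), without a variance trend (0.054), with array weights (0.051) and with median-of-ratios scaling (0.051). The mt-Nd1 locus also carries the name of mt-Ti, and passed without a variance trend (adjusted p = 0.042), and mt-Nd6 passed with array weights (adjusted p = 0.021). Of the 8 mtDNA-encoded mRNA loci with a value in every library, 2 were lower, mt-Cytb and mt-Nd3, and 1 was lower adjusted over the list alone. These 8 loci did not pass camera (adjusted p = 0.17). Their control means ranged from 33.0 to 25193 FPKM, and whether the lowest are sound estimates was not tested. With no filter on low values mt-Cytb did not pass (adjusted p = 0.22, against 0.00023 to 0.021 in the other alternatives), with its fold change as before.

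**Figure D1:**
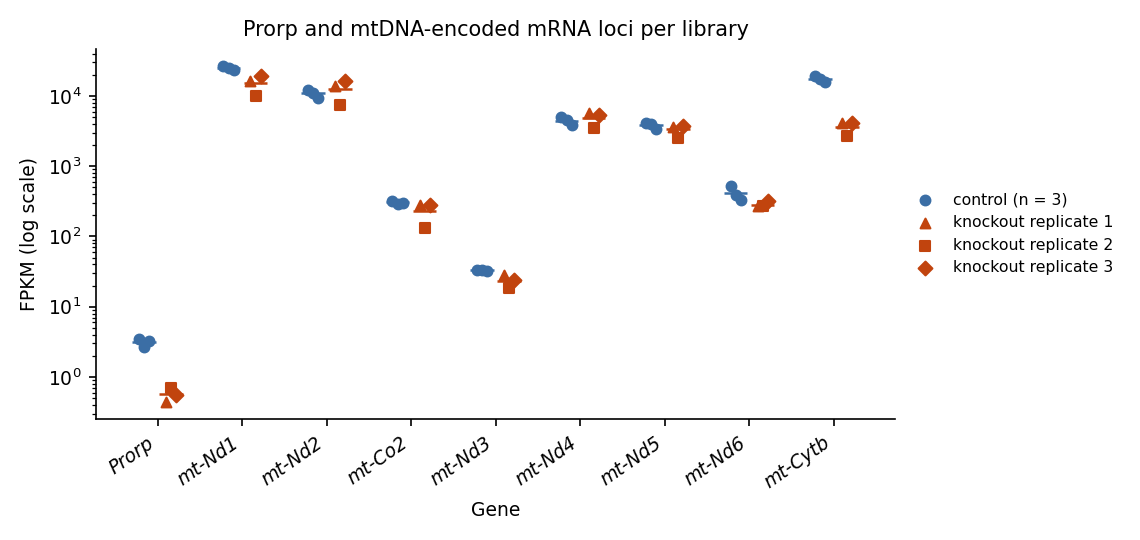
FPKM (log axis) of Prorp and of the 8 mtDNA-encoded mRNA loci with a value above 0 in all 6 libraries; points are libraries and horizontal lines are means of 3. Prorp and mt-Cytb are lower in all 3 knockout libraries than in all 3 controls, while mt-Nd2 and mt-Nd4 overlap.

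Several very abundant loci were listed at exactly 0 in some libraries, so for them only the listed values are given. mt-Rnr1, the small mitochondrial rRNA, was listed at 0 in all 3 controls and at 18520, 12603 and 19692 FPKM in the knockouts. mt-Rnr2 was listed at 0 in all 6 libraries, as were 19 of the mitochondrial tRNA loci, and mt-Co1 was listed only in knockout replicate 2, at 19583 FPKM. The merged locus of mt-Atp6, mt-Atp8 and mt-Co3 had 351, 332 and 357 FPKM in controls, was listed at 0 in knockout replicates 1 and 3, and had 167 FPKM in knockout replicate 2. Ttn, which encodes the giant sarcomere protein titin, had 1662 FPKM in control replicate 1 and 774 in knockout replicate 2 and was listed at 0 in the other libraries. The share of all FPKM taken by the 31 mtDNA-encoded loci was 11.3 ± 1.69% in controls and 13.2 ± 0.278% in knockouts, and the exact two-sided permutation p of 0.20 compares with a smallest possible value of 0.10. This share counts listed zeros as they stand, so mt-Rnr1 adds to the knockouts only and the higher knockout share rests on it. Over the protein-coding mtDNA loci alone, the order was opposite, with 11.3 ± 1.69% in controls and 9.74 ± 0.391% in knockouts (exact permutation p = 0.20). These still include mt-Co1 and the merged locus with listed zeros. Over the 8 loci with a value in every library, an alternative chosen after seeing the data, the order was also opposite, with 11.2 ± 1.69% in controls and 8.29 ± 2.12% in knockouts (exact permutation p = 0.10). The knockout libraries stood at 9.41, 5.84 and 9.62%, so knockout replicate 2 enlarged this difference.

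Across the transcriptome 4343 of the 12181 loci differed, 1966 higher and 2377 lower in the knockout (limma, adjusted p under 0.05). Without the 4 abundant loci with listed zeros the counts were 1965 and 2376. Other loci listed at 0 in some libraries stayed in, among them Adm2 and Ostn. Of the 4343 loci, 706 were at least 2-fold higher and 823 at least 2-fold lower. Counts of list members below are to be read beside these counts over all loci. The 8 largest rises were led by Lgals3, which encodes galectin-3, a lectin abundant in activated macrophages. It rose from 1.07 ± 0.188 to 137 ± 54.9 FPKM (log2 fold change 6.38, SE 0.29, limma adjusted p = 4.7e-05). Next came Asns (asparagine synthetase), Mthfd2 (mitochondrial folate enzyme), Gdf15 (a secreted stress cytokine), Nppa (atrial natriuretic peptide), Phgdh (first step of serine synthesis), Maoa (monoamine oxidase A) and Nmrk2 (nicotinamide riboside kinase). The order depends on the pseudocount, and at 0.1 Gdf15 (6.97) stood above Lgals3 (6.81). Maoa rose from 0.607 ± 0.0848 to 47.5 ± 30.7 FPKM and Nmrk2 from 2.54 ± 0.590 to 178 ± 159 FPKM, with knockout libraries at 340, 171 and 23.1. The largest falls were of Ces1d (a carboxylesterase), from 64.2 ± 9.80 to 1.54 ± 0.820 FPKM (log2 fold change -5.07, SE 0.30, limma adjusted p = 0.00013), and Efnb3 (ephrin-B3), from 19.5 ± 2.33 to 0.451 ± 0.263 FPKM. Rpl3l, a ribosomal protein made in striated muscle, fell from 86.7 ± 10.8 to 5.18 ± 3.03 FPKM. Lrtm1, Pla2g5 and Gpr22 fell by 3.90, 3.62 and 3.58 on the log2 scale. Hspa1b and Hspa1a, near-identical genes of the inducible chaperone HSP70 whose fragments cannot be reliably told apart, fell by 3.91 and 3.81. Scaling every library to the same summed FPKM moved the median log2 fold change of all tested loci from -0.02 to 0.20 and gave 3229 higher and 1400 lower, and removing mtDNA-encoded loci before such scaling gave a median of 0.22 with 3380 higher and 1288 lower. Without control replicate 1, 2 or 3 the counts were 1276, 1212 and 1315 higher and 1529, 1409 and 1470 lower.

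Knockout replicate 2 stood apart from the other libraries in transcripts of atrial muscle and blood and in lower levels of muscle and metabolic genes. Myl7, the atrial regulatory light chain, had 911 FPKM in that library against 43.5 and 0.0961 in knockout replicates 1 and 3 and at most 1.90 in controls. Hbb-bs, a beta-globin, had 13872 FPKM there against 378 and 1188 in the other knockouts. Myl3, a ventricular light chain, had 226 FPKM there against 1637 and 1334. Against the mean of knockout replicates 1 and 3, the median of the list was -0.68 on the log2 scale for adult contractile genes, -0.61 for complex I and -1.01 for fatty acid uptake and oxidation. Without this library 2153 loci were higher and 2389 lower, and 3893 of the 4343 calls were also made in the same direction.

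**Figure D2:**
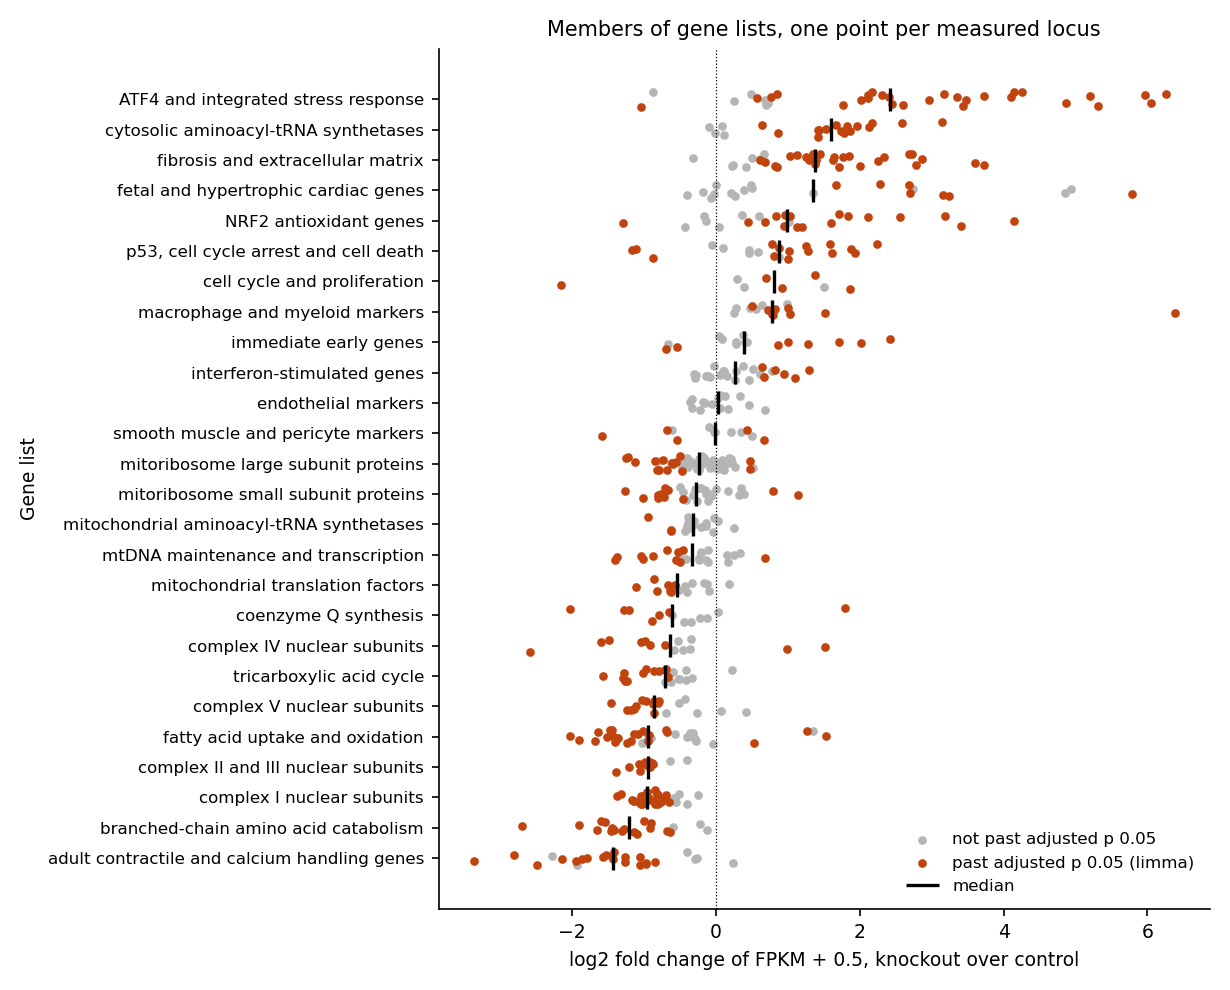
Log2 fold change (FPKM + 0.5, knockout over control) of every measured member of the 24 gene lists past the camera threshold and of endothelial and smooth muscle markers; red points passed limma adjusted p under 0.05 and black bars are medians. The stress-response list sits highest, with a median of 2.43, and the adult contractile list lowest, with a median of -1.43, while endothelial markers centre on 0.03.

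Genes of the integrated stress response, the program run by the transcription factor ATF4 when translation or amino acid supply is disturbed, rose together. Of 34 measured members 27 rose, 1 fell (Vldlr) and 6 did not pass, and 31 rose and 1 fell when adjusted over the list alone. With 1 library left out the number that fell was 0, except without knockout replicate 3, where it was 2. Asns rose from 0.969 ± 0.442 to 111 ± 21.9 FPKM (log2 fold change 6.26, SE 0.23, limma adjusted p = 2.2e-05) and Mthfd2 from 0.754 ± 0.116 to 82.8 ± 8.50 FPKM (log2 fold change 6.05, SE 0.13, limma adjusted p = 1e-06). Gdf15 rose from 0.295 ± 0.0637 to 62.0 ± 46.5 FPKM, with single knockout libraries at 56.2, 18.7 and 111. Phgdh rose from 0.743 ± 0.271 to 49.5 ± 14.5 FPKM. This list had a median log2 fold change of 2.43 and a camera adjusted p of 4.4e-17, or an adjusted p = 0.49 with an estimated correlation, and fry gave an adjusted p of 0.0031. The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation outside mitochondria, also rose, 16 of 20 over all loci and 16 when adjusted over the list alone. Gars (glycyl-tRNA synthetase) went from 20.1 ± 1.28 to 185 ± 42.3 FPKM, Sars (seryl) from 28.4 ± 3.26 to 175 ± 37.5, Nars (asparaginyl) from 22.3 ± 1.44 to 103 ± 22.3 and Eprs (glutamyl and prolyl) from 33.0 ± 0.911 to 150 ± 41.8. The camera adjusted p for this list was 4.9e-10, or an adjusted p = 0.55 with an estimated correlation, and fry 0.0051.

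**Figure D3:**
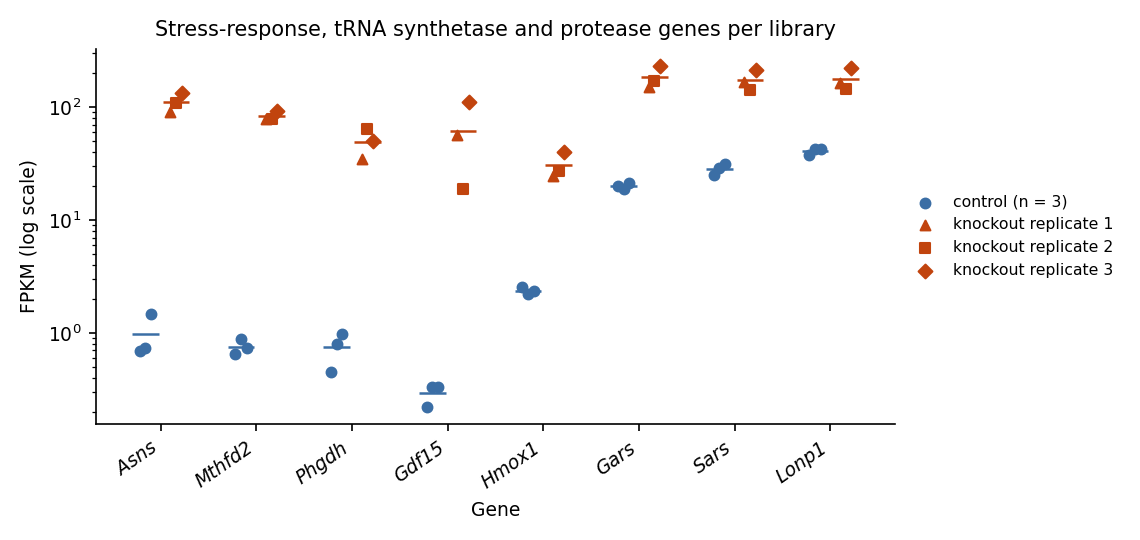
FPKM (log axis) per library of 4 stress-response genes, Hmox1, 2 cytosolic tRNA synthetases and the mitochondrial protease gene Lonp1; points are libraries and horizontal lines are means of 3. All 3 knockout libraries lie above all 3 controls for each gene, from 0.969 to 111 FPKM on average for Asns.

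Nuclear genes of the respiratory chain were lower in the knockout. For complex I, 30 of 36 measured subunit genes fell (34 adjusted over the list alone) and none rose, with a median log2 fold change of -0.96. Ndufs1, which carries iron-sulfur clusters, fell from 290 ± 16.2 to 112 ± 23.8 FPKM (log2 fold change -1.38, SE 0.19, limma adjusted p = 0.0020), and Ndufv3 from 502 ± 37.4 to 205 ± 57.1 FPKM. Camera gave an adjusted p of 1.6e-09 for complex I, or an adjusted p = 0.73 with an estimated correlation. For complexes II and III, 11 of 13 fell (12 adjusted over the list alone), among them Uqcr11, from 1035 ± 92.2 to 405 ± 111 FPKM, and Sdha of complex II, from 368 ± 32.3 to 180.0 ± 47.6. The camera adjusted p for this list was 0.00014, or an adjusted p = 0.73 with an estimated correlation. For complex V, 12 of 18 fell (14 adjusted over the list alone), among them Atp5k, from 1217 ± 63.7 to 451 ± 118 FPKM. For this list the camera adjusted p was 0.0003, or an adjusted p = 0.73 with an estimated correlation. For complex IV, 7 of 14 fell and 2 rose (8 and 2 adjusted over the list alone). Cox7a1 and Cox8b, the isoforms made in heart and muscle, fell from 2302 ± 101 to 401 ± 152 and from 1285 ± 67.3 to 448 ± 171 FPKM. Cox6a1, the isoform of most other tissues, rose from 97.5 ± 10.9 to 281 ± 54.8 FPKM, and Cox8a rose by 0.98 on the log2 scale. The camera adjusted p of 0.025 for complex IV became 0.092 after quantile normalization, and the adjusted p = 0.73 with an estimated correlation. Fewer genes were lower without control replicate 2 or 3, with 15 and 14 for complex I, 4 and 4 for complexes II and III and 5 and 5 for complex V, which had 7 without control replicate 1 and 1 gene higher without knockout replicate 2. Fry passed for complex I (adjusted p = 0.048) and for complexes II and III (0.050, below the threshold before rounding), and not for complex V (0.060) or complex IV (0.10).

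Many genes of fuel oxidation were lower, while a few rose. Of 35 genes of fatty acid uptake and oxidation, 19 fell and 3 rose (23 and 4 adjusted over the list alone). Acaa2, the last enzyme of the mitochondrial β-oxidation cycle, fell from 516 ± 34.8 to 133 ± 47.9 FPKM (log2 fold change -2.03, SE 0.28, limma adjusted p = 0.0021). Lpl (lipoprotein lipase) fell from 962 ± 48.3 to 289 ± 169 FPKM, Hadh from 250 ± 5.87 to 83.4 ± 27.0, and Ppara, the fatty acid-sensing nuclear receptor, from 22.9 ± 0.949 to 6.89 ± 1.55. The 3 list members that rose were Acot2, Acaca and Cpt1a, by 1.53, 1.27 and 0.52 on the log2 scale, of which Acaca encodes an enzyme of fatty acid synthesis. Without any one control 12 fell and 1 rose, and 5 rose without knockout replicate 2, where the median moved from -0.94 to -0.58. The list passed camera (adjusted p = 0.00026) and had an adjusted p = 0.73 with an estimated correlation, and it did not pass fry (0.12). Branched-chain amino acid catabolism had 17 of 20 genes lower, the same number when adjusted over the list alone, with a median log2 fold change of -1.22. Ppm1k, the phosphatase that activates the branched-chain ketoacid dehydrogenase, fell from 38.7 ± 4.52 to 5.56 ± 0.734 FPKM, and Ivd from 120 ± 4.89 to 32.7 ± 10.1. For this list the camera adjusted p was 1.9e-08, or an adjusted p = 0.59 with an estimated correlation, and fry gave 0.0078. In the tricarboxylic acid cycle list 12 of 21 genes fell, also 12 adjusted over the list alone, including Mpc2 of the mitochondrial pyruvate carrier, from 309 ± 17.5 to 128 ± 29.1 FPKM, and Me3, from 52.7 ± 2.19 to 21.8 ± 4.68. The number that fell was 6, 4 and 5 without control replicates 1, 2 and 3 in turn, and 1 rose without knockout replicate 2. The camera adjusted p for the cycle was 8.1e-05, or an adjusted p = 0.73 with an estimated correlation, and it did not pass fry (0.078). Coenzyme Q synthesis had 6 of 13 loci lower and 1 higher (7 and 1 adjusted over the list alone). Adck3 fell from 260 ± 26.0 to 65.3 ± 19.6 FPKM, and Coq9 from 215 ± 14.9 to 94.6 ± 23.9, while a merged locus of Adck4 and Numbl rose from 3.95 ± 0.611 to 15.1 ± 4.22, which cannot be assigned to either gene. The median of the list moved from -0.62 to -0.35 without knockout replicate 2. Its camera adjusted p was 0.026, or an adjusted p = 0.73 with an estimated correlation, and it did not pass fry (0.094). Glycolysis and lactate genes went both ways, 9 higher and 7 lower of 25 (10 and 9 adjusted over the list alone), with no shift of the list (camera adjusted p = 0.64). Pfkp and the lactate exporter Slc16a3 rose, from 17.0 ± 3.36 to 74.4 ± 27.1 and from 0.648 ± 0.107 to 3.87 ± 0.464 FPKM. The muscle enolase Eno3 fell from 747 ± 25.7 to 148 ± 41.9 FPKM.

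In the list of mtDNA maintenance and transcription 10 of 24 loci fell and 1, Tk2, rose (11 and 1 adjusted over the list alone), with a median log2 fold change of -0.33. Ppargc1a, the coactivator of mitochondrial biogenesis, fell from 48.6 ± 17.8 to 17.8 ± 1.66 FPKM, Mterf2 from 15.8 ± 0.482 to 5.75 ± 1.22 and Dguok, which makes nucleotides for mtDNA, from 19.2 ± 1.27 to 9.30 ± 1.17. Its camera adjusted p was 0.0096, or an adjusted p = 0.49 with an estimated correlation, and fry gave 0.0061. Mitochondrial translation factors had 7 of 16 genes lower and none higher (11 adjusted over the list alone), including Tufm, the elongation factor Tu, from 33.7 ± 3.78 to 15.4 ± 2.85 FPKM. Without control replicate 2 the number lower was 4. With camera the adjusted p was 0.0023, or an adjusted p = 0.73 with an estimated correlation, and fry gave 0.050, below the threshold before rounding. Among proteins of the large mitoribosome subunit 13 of 52 genes fell and 2, Mrpl52 and Mrpl24, rose (12 and 2 adjusted over the list alone), and among those of the small subunit 10 of 30 fell and 2, Mrps18b and Mrps10, rose (11 and 2). Mrpl42 fell from 266 ± 22.8 to 114 ± 19.4 FPKM and Mrps35 from 66.9 ± 3.50 to 27.8 ± 4.46, while Mrps18b rose from 13.2 ± 1.04 to 30.2 ± 7.22. Their medians were -0.24 and -0.28, and the first turned to 0.02 once mtDNA-encoded loci were removed before scaling to one sum. Camera adjusted p was 0.024 and 0.029, or an adjusted p = 0.79 and 0.74 with an estimated correlation, and neither passed fry (0.21 and 0.12). Both calls were lost under that scaling (adjusted p = 0.057 and 0.052) and without knockout replicate 2 (adjusted p = 0.27 and 0.16), where 6 and 5 genes rose and the medians were -0.14 and -0.17, and that of the small subunit without control replicate 3 (0.056). Of the large subunit 7, 7 and 6 genes fell and 0, 0 and 1 rose without control replicates 1, 2 and 3 in turn, and 1 rose without knockout replicate 3. Of 17 mitochondrial tRNA synthetases 3 fell, also 3 adjusted over the list alone, led by Cars2, from 13.6 ± 0.707 to 6.78 ± 0.410 FPKM, then Hars2 and Fars2. Over all 12181 tested loci 2377 fell, a share no smaller than 3 of 17. Hars2 did not pass without control replicate 3 (adjusted p = 0.066), nor Fars2 without any one control (0.061, 0.058 and 0.054). Under the 2 scalings to a sum neither passed (0.13 and 0.10 for Hars2, 0.079 and 0.051 for Fars2). The number that fell was 1 without control replicate 3 and 5 without knockout replicate 1. The camera adjusted p of 0.037 for the list, or an adjusted p = 0.73 with an estimated correlation, became 0.13 without knockout replicate 2, 0.088 without control replicate 3, and 0.098 and 0.080 under the 2 scalings to a sum, and the list did not pass fry (0.057). Mitoribosome assembly factors had 9 of 26 loci lower and 1 higher, the same adjusted over the list alone, with no call for the list (camera adjusted p = 0.070). Of these, 4, 3 and 4 fell without control replicates 1, 2 and 3 in turn, and 2 rose without knockout replicate 2. Mtg2 fell from 14.5 ± 1.26 to 8.63 ± 0.903 FPKM and Mpv17l2 rose from 4.64 ± 0.942 to 11.0 ± 2.00. In the list of mitochondrial RNA stability and decay 5 of 18 loci fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.062). Without any one control 2 of these fell, 3 fell without knockout replicate 1, and 2 rose without knockout replicate 2. Fastkd1 fell from 11.2 ± 0.378 to 6.09 ± 0.642 FPKM, and the oligoribonuclease Rexo2 rose from 21.4 ± 1.22 to 40.9 ± 8.52. Mitochondrial chaperones and proteases had 5 of 20 loci higher and 1 lower, the same adjusted over the list alone. Lonp1, the main matrix protease, rose from 40.9 ± 2.80 to 176 ± 39.1 FPKM (log2 fold change 2.08, SE 0.18, limma adjusted p = 0.00042), Htra2 rose from 8.01 ± 0.869 to 17.0 ± 0.255, and Oma1 fell from 16.1 ± 0.928 to 7.91 ± 1.70. This list did not pass camera (adjusted p = 0.23) but did without knockout replicate 2 (0.012, 9 loci higher). The number higher was 3, 2 and 3 without control replicates 1, 2 and 3 in turn and 3 without knockout replicate 1, and 3 were lower without knockout replicate 3.

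Adult contractile and calcium-handling genes fell, 19 of 25 over all loci and 20 adjusted over the list alone, with none higher and a median log2 fold change of -1.43. Without control replicate 2 or 3 the number lower was 11. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell from 348 ± 13.2 to 35.3 ± 14.1 FPKM (log2 fold change -3.37, SE 0.31, limma adjusted p = 0.00050). Pln (phospholamban), which restrains the calcium pump, fell from 2309 ± 98.6 to 362 ± 171 FPKM, and the potassium channel gene Kcnd2 from 10.1 ± 3.22 to 1.38 ± 0.531. Myl3 passed at a limma adjusted p of 0.048, was far lowest in knockout replicate 2, and did not pass without any one control (adjusted p = 0.10, 0.11 and 0.13), with no filter (0.12), under 3 of the scalings (0.055 to 0.094) or with the robust variance model (0.055). The camera adjusted p for the list was 4.4e-07, or an adjusted p = 0.58 with an estimated correlation, and fry 0.0078. Of 21 fetal and hypertrophic cardiac genes 7 rose, also 7 adjusted over the list alone, and none fell. Nppa rose from 72.2 ± 41.8 to 4934 ± 4848 FPKM, with knockout libraries at 1948, 10527 and 2327, the highest being the library rich in atrial transcripts. Nppb (B-type natriuretic peptide) rose from 101 ± 70.4 to 762 ± 364 FPKM, Ankrd1 from 293 ± 131 to 1784 ± 362 and Uchl1 from 5.11 ± 0.465 to 63.0 ± 48.1. With camera the adjusted p was 0.00044, or an adjusted p = 0.49 with an estimated correlation, fry gave 0.011, and without knockout replicate 2 there were 12 genes higher. Extracellular matrix and fibrosis genes rose, 26 of 33 over all loci, with 29 higher and 1 lower adjusted over the list alone. Cilp, a cartilage matrix protein gene, rose from 1.38 ± 0.223 to 25.4 ± 15.1 FPKM, Tgfb2 from 1.37 ± 0.605 to 13.5 ± 6.17 and Comp from 0.521 ± 0.143 to 7.00 ± 3.18. For this list the camera adjusted p was 1.9e-11, or an adjusted p = 0.45 with an estimated correlation, and fry 0.0031.

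Antioxidant genes controlled by NRF2 rose, 16 of 24 with 1, Sod2, lower, the same adjusted over the list alone, and 2 lower without knockout replicate 3. Slc7a11, the cystine importer also counted in the ATF4 list, was at most 0.0220 FPKM in controls and 8.74 ± 2.79 in knockouts. Hmox1 (heme oxygenase) rose from 2.37 ± 0.171 to 30.6 ± 8.40 FPKM, the metallothionein Mt2 from 5.80 ± 2.39 to 54.3 ± 9.53 and Srxn1 from 6.74 ± 0.734 to 42.9 ± 10.6. With camera the adjusted p was 9.2e-07, or an adjusted p = 0.69 with an estimated correlation, and fry gave 0.0096. In the list of p53 targets, arrest and cell death 12 of 21 rose and 3, Ccng1, Fas and Sesn1, fell (13 and 3 adjusted over the list alone). Gadd45a rose from 5.64 ± 0.704 to 29.6 ± 10.5 FPKM, Phlda3 from 4.29 ± 0.682 to 17.7 ± 0.546 and the cell cycle inhibitor Cdkn1a from 6.98 ± 2.12 to 23.5 ± 11.7. Its camera adjusted p was 0.00017, or an adjusted p = 0.49 with an estimated correlation, and fry gave 0.0061. Of 8 measured cell cycle genes 4 rose and 1, Cenpf, fell, the same adjusted over the list alone. The number of cell cycle genes that rose was 1 without any one control, 2 without knockout replicate 1 or 2, 7 without knockout replicate 3 and 1 with the replicate block. Ccnd2 rose from 10.6 ± 1.74 to 39.9 ± 6.28 FPKM, and Cenpf fell from 5.18 ± 1.92 to 0.879 ± 0.698. Of 16 immediate early genes 6 rose and 2, Klf4 and Klf2, fell, the same adjusted over the list alone, with Junb up from 4.04 ± 0.475 to 14.6 ± 3.69 FPKM. Without any one control or knockout replicate 1 only 3 immediate early genes rose, and 0 fell without any one control and 1 without any one knockout. Of 24 interferon-stimulated genes 6 rose and none fell (5 adjusted over the list alone), led by Zbp1, from 0.340 ± 0.105 to 1.56 ± 0.177 FPKM. Only 3 interferon genes rose without control replicate 1 or knockout replicate 1, and 2 without control replicate 3. These 3 lists each had a camera adjusted p of 0.042, or an adjusted p = 0.73, 0.73 and 0.74 with an estimated correlation, and none passed fry (0.10, 0.12 and 0.21). All 3 calls were lost without knockout replicate 2 (adjusted p = 0.14, 0.16 and 0.27) and without knockout replicate 1 (0.088, 0.082 and 0.083). The cell cycle call was also lost without control replicate 1 (0.053) or 2 (0.058), that of immediate early genes without control replicate 2 (0.063), and that of interferon genes without control replicate 1 (0.066) or 3 (0.091), and all 3 under each of the 4 scalings (0.051 to 0.19). Autophagy genes went both ways, 5 higher and 4 lower of 20 (5 and 5 adjusted over the list alone, camera adjusted p = 0.65). The number that rose was 3, 2 and 3 without control replicates 1, 2 and 3 in turn, and 2 fell without any one of them or knockout replicate 1. The lysosomal protease Ctsl rose from 58.3 ± 1.04 to 305 ± 118 FPKM and the receptor Sqstm1 from 131 ± 9.20 to 588 ± 198, while the locus of Pink1 and 2 small RNA genes fell from 223 ± 14.5 to 73.2 ± 21.5. Of 17 circadian clock genes 5 rose and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.29). Clock genes that rose numbered 2, 1 and 3 without control replicates 1, 2 and 3 in turn, and 3 without knockout replicate 1, while 1 fell without control replicate 1 or 2 or knockout replicate 1 and 4 without knockout replicate 3. Arntl fell from 10.4 ± 0.840 to 1.77 ± 1.90 FPKM, with knockout libraries at 0.570, 0.777 and 3.96, and Ciart rose from 2.28 ± 0.456 to 10.3 ± 0.661.

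Among markers of other cell types, those of macrophages and myeloid cells rose, 11 of 17 over all loci and adjusted over the list alone, with none lower. Ccr2, a receptor of recruited monocytes, rose from 0.431 ± 0.128 to 2.16 ± 0.403 FPKM, Cd68 from 3.43 ± 0.289 to 7.33 ± 0.664 and Itgam from 0.877 ± 0.0785 to 2.36 ± 0.654. The list passed camera (adjusted p = 1.7e-06) and had an adjusted p = 0.49 with an estimated correlation, and fry 0.0061. Endothelial markers gave no call in 15 measured loci, also none adjusted over the list alone, and 2 loci had an unadjusted limma p under 0.05. Their median log2 fold change was 0.03, and without knockout replicate 2 Tek passed (log2 fold change -0.42, adjusted p = 0.037), while 1 locus was lower without knockout replicate 3. Fabp4 had 310 ± 26.1 FPKM in controls and 250 ± 54.6 in knockouts, and the merged Egfl7 locus 133 ± 12.2 and 140 ± 27.3. Smooth muscle and pericyte markers had 2 of 12 higher and 3 lower, the same adjusted over the list alone, with Abcc9 down from 77.4 ± 3.38 to 26.1 ± 6.44 FPKM and Cspg4 up from 4.03 ± 0.435 to 6.72 ± 0.749. Without any one control 1 was higher and 1 lower. Fibroblast markers had 5 of 13 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.27). Of these 2 were higher without any one control and 3 without knockout replicate 1, and 1 was lower without any one library except knockout replicate 2. Col1a1 rose from 5.71 ± 1.24 to 25.8 ± 11.7 FPKM and Mfap5 from 8.37 ± 1.61 to 30.2 ± 10.6, while Scara5 fell from 6.16 ± 0.963 to 1.02 ± 0.649. Of the 4 measured neuronal and Schwann cell markers 2 rose and 2 fell, the same adjusted over the list alone, with Ncam1 up from 1.64 ± 0.577 to 12.7 ± 9.34 FPKM, and 0 fell without any one control and 1 without knockout replicate 1 or 3. Atrial markers had 2 of 10 higher and 1 lower, also adjusted over the list alone, with 5 lower without knockout replicate 2 and 4 higher without knockout replicate 3. Dkk3 rose to 5.77, 100 and 3.01 FPKM in the knockout libraries from 0.458 ± 0.139 in controls, a call lost without any one control (adjusted p = 0.079, 0.088 and 0.091), with no filter (0.080) and with the robust variance model (0.095). None of 7 erythroid, 2 lymphocyte and 3 adipocyte loci passed over all loci, and 1 lymphocyte locus, the only one of these with an unadjusted limma p under 0.05, passed adjusted over the list alone. A lymphocyte locus passed without knockout replicate 3. The adipocyte gene Cidea passed with array weights (adjusted p = 0.014) and without knockout replicate 2 (0.012), as did the skeletal muscle gene Myl1 without that library (0.017). Of 2 skeletal muscle loci, Tnni2 fell, and of 4 sex-linked loci, the Y-linked Uty fell from 15.9 ± 1.47 to 10.2 ± 0.616 FPKM, both also when adjusted over the list alone, and 2 sex-linked loci fell without knockout replicate 3. Of the mitochondrial tRNA list 2 loci were measured, both merged with mRNA loci given above, and neither passed.

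**Figure D4:**
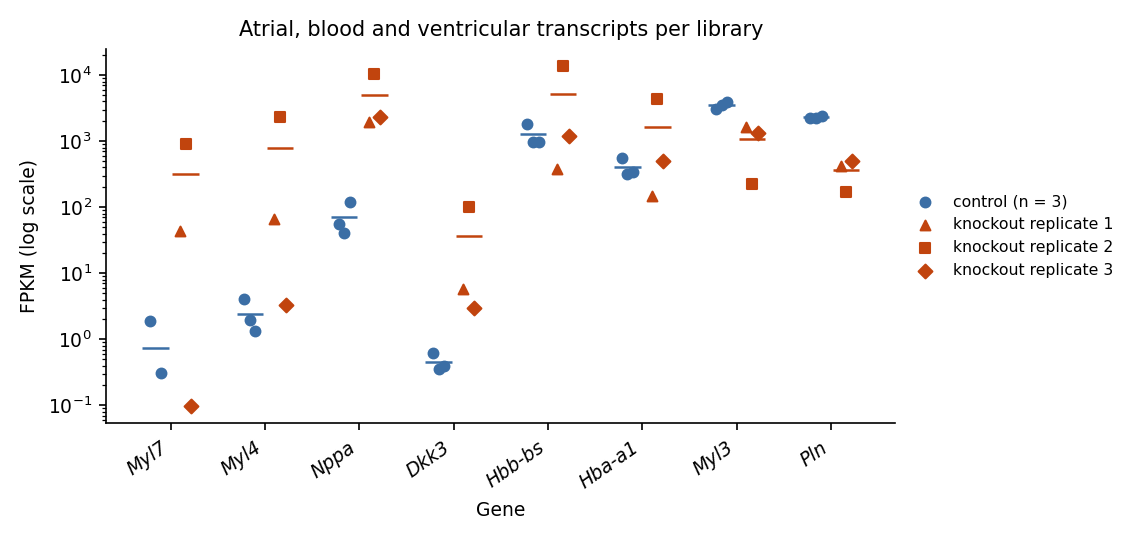
FPKM (log axis) per library of atrial (Myl7, Myl4, Nppa, Dkk3), blood (Hbb-bs, Hba-a1) and ventricular (Myl3, Pln) transcripts; points are libraries, horizontal lines are means of 3, and Myl7 is not drawn in control replicate 2, where it is listed at 0. Knockout replicate 2 is highest for the atrial and blood genes, with 911 FPKM of Myl7, and lowest for Myl3, with 226 FPKM.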

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

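The tests in this part were chosen after the results were seen, except the counts over other splits of the libraries. Both counts of calls were repeated over all 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05. For loci, the real split gave 4343 calls and the highest of the other splits 3, so 1 split reached the real count. For gene lists, the real split gave 24 camera calls and the highest of the others 27, and 3 splits, the real one included, gave as many. Every other split mixes both genotypes on each side. A genotype difference then adds to the spread within sides, which by itself leaves few locus calls, and part of it stays between sides for the lists. Neither count therefore measures what unrelated libraries would give.

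Knockout replicate 2 carried transcripts of atrial muscle far above the other knockouts. The median difference of the 12 fixed atrial markers, against the mean of knockout replicates 1 and 3, was 3.77 on the log2 scale, with 10 of them above 1. Its ventricular light chains Myl2 and Myl3 differed by -2.85 and -2.71, as atrial tissue in the dissected sample would give, and its most abundant atrial transcripts were Nppa at 10527 and Myl4 at 2290 FPKM. A mislabelled sample is argued against by Prorp, at 0.701 FPKM there against 2.64 in the lowest control. The ATF4 list gave no sign of a stronger stress response in this sample, with a difference of -0.10. This is less than the 0.65 by which knockout replicates 1 and 3 differed from each other, so that explanation stays open. Apart from this question, the 9 erythroid markers were higher in knockout replicate 2 by a median of 3.98.

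The 106 measured genes of the contractile list and the 4 nuclear respiratory chain lists had a median log2 fold change of -0.97, and 79 of them fell, or 40 and 39 without control replicate 2 or 3, where the medians were -0.96 and -0.94. A lower share of cardiomyocytes with all other cell types kept in proportion would raise their markers alike. Against that case, the macrophage list rose by 1.06 more than the endothelial list (SE 0.18), which itself moved by 0.02 (SE 0.05). The 1.06 is a difference of list means, and the median log2 fold change of the macrophage list was 0.78. Lgals3, the largest rise of all (log2 fold change 6.38), is a member of that list and raises its mean. A lower share through a gain of only some cell types is not tested by this and stays open. The atrial content of knockout replicate 2 is not the whole cause, since the median without it was -0.75 with 84 genes lower. Knockout replicate 1, kept in that fit, also held Myl7 and Myl4 above controls (43.5 and 66.1 FPKM, against at most 1.90 and 4.09). Knockout replicate 3 did not (0.0961 and 3.35 FPKM). Scaling between libraries is not the whole cause either, since the alternative that brought the median closest to 0, quantile normalization, left it at -0.65 (median SE 0.15). Loss of Prorp, or Cre, is a candidate explanation for what remains, as a hypothesis, beside such a change in cell types. These cannot be separated by this design.

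mt-Cytb fell while mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5, mt-Nd6 and mt-Co2 did not pass the test. A uniform loss of mitochondrial transcripts as the whole cause is argued against by the log2 ratio of mt-Cytb, a locus picked because it fell, to the mean of all 7 other mtDNA-encoded mRNA loci above 0 in every library, which differed by -1.96 between knockouts and controls (SE 0.02), while the 7, each set against the others without mt-Cytb, ranged from -0.54 for mt-Nd1 (SE 0.10) to 0.55 for mt-Nd2 (SE 0.15) and their median log2 fold change of the 7 was -0.49, or -0.13 without knockout replicate 2. Whether fragments were assigned instead to nuclear copies cannot be judged from the 6 nuclear copy loci, since they include 0 annotated as a copy of mt-Cytb. Their sums were 3145 FPKM on average in controls and 1426 in knockouts (at most 1969, against a loss of 13811 at mt-Cytb). FPKM are scaled to transcript length, so such sums are not fragment counts. Copies at these loci or elsewhere stay open, since no sequence was examined. Estimates that failed at abundant mitochondrial loci stay open, because 3 mtDNA-encoded loci were listed at 0 in some libraries and above 0 in others and no reads were used here. The loss of Prorp, or Cre, stays among the open explanations, as untested.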

How the results depend on the processing

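The alternatives were fixed before the data were examined, except those without the 4 abundant loci with listed zeros and over the mtDNA-encoded loci above 0 in every library. The 1966 loci higher in the knockout became 1303 with a mean of at least 5 FPKM (fewer loci tested), 3380 with mtDNA-encoded loci removed and the rest scaled to one sum, and 3229 scaled to a sum of 1000000. The 2377 lower became 1288 and 1400 under these scalings, which raise the median of all loci by about 0.2 (to 0.22 and 0.20). Leaving out 1 library gave 1212 to 2153 higher and 1409 to 2389 lower. The 24 list calls became 0 with an estimated correlation and 13 with fry, and 19 to 27 with 1 library left out, and 17 of the 24 lists passed under every other alternative (cell cycle genes, not among the 17, were not tested with a mean of at least 5 FPKM). The difference of 2.00 percentage points in the mtDNA-encoded share (1.23 to 2.91 with 1 library left out) reversed to -1.52 for protein-coding genes only, -1.17 with rRNAs and tRNAs left out and -2.90 over loci above 0 in every library. These alternatives leave out mt-Rnr1, listed at 0 in controls. They were not repeated with 1 library left out and lean on single libraries. For protein-coding genes the shares were 13.1, 11.0 and 9.73% in controls and 9.41, 10.2 and 9.62% in knockouts. Over loci above 0 in every library, knockout replicate 2 was far lowest, at 5.84%. The p of the share cannot pass, so it says nothing about stability.

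Of the 148 named loci past the threshold, 125 were tested in every alternative, and 106 of these passed in each. The other 23 were missing from at least 1 alternative, by its filter or its removal of mtDNA-encoded loci, and 12 of them passed in each that tested them. None of the 148 changed sign where tested. Of the named loci that did not pass, some reversed. With 1 library left out the log2 fold changes ranged from -0.0852 to 0.48 for the locus listed as mt-Nd2,mt-Tw, -0.0252 to 0.31 for mt-Nd4,mt-Nd4l, -0.0296 to 0.23 for Egfl7,Fam69b,Gm20532,Mir126a, -0.25 to 0.54 for Igkc, -0.85 to 1.75 for Hbb-bs and -0.54 to 1.88 for Hba-a1, the last 3 below 0 without knockout replicate 2. With array weights these 3 stood at -0.13, -1.03 and -0.77. After quantile normalization mt-Nd5 stood at 0.42 and Fabp4 at 0.00684, and mt-Nd5 at 0.00655 scaled to a sum of 1000000. The cause was not tested. The replicate block gave 1536 higher, 1807 lower and 24 lists, with 3265 calls shared. Same-numbered libraries did not deviate together (correlations of -0.08, -0.06 and -0.01), so the numbers were not taken as pairs, and no library correlated best with its own number. Low values are least precise in the controls, whose libraries were shallower.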

Other observations

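The genes in this part were chosen after their values were seen. Beside the loss of Rpl3l, the locus of its ubiquitous paralog Rpl3 (merged with Gm22077) rose from 22.3 ± 3.66 to 94.3 ± 3.13 FPKM (log2 fold change 2.07, SE 0.15, limma adjusted p = 0.00024). Heat-shock genes went both ways. Hsph1 fell from 26.0 ± 4.15 to 8.50 ± 2.51 FPKM and Dnajb1 from 19.2 ± 3.90 to 6.22 ± 0.808, along with the HSP70 pair, while the small heat-shock gene Hspb1 rose from 113 ± 15.4 to 203 ± 51.7 and the merged Hspa8 locus did not pass the test (limma adjusted p = 0.31). Ostn (osteocrin) was listed at 11.9, 9.42 and 21.5 FPKM in the knockouts, at 0.0538 in control replicate 2 and at 0 in the other controls. Adm2 was listed at 0 in all 3 controls and at 6.15, 4.45 and 8.38 FPKM in the knockouts, and Fgf21 had 2.78, 1.87 and 13.3 FPKM in the knockouts and at most 0.0886 in controls. Myoglobin (Mb) fell from 6577 ± 452 to 1907 ± 917 FPKM.

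The RNA subunits of the nuclear ribonucleases did not pass the test. Rpph1, of nuclear RNase P, had 8617 ± 2157 FPKM in controls and 11969 ± 2212 in knockouts (limma adjusted p = 0.35), and Rmrp had 4945 ± 1281 and 6747 ± 977 (limma adjusted p = 0.32). Dlg2, a scaffold protein gene best known from synapses, rose from 0.785 ± 0.0323 to 32.4 ± 3.16 FPKM, and the teneurin gene Tenm4 from 0.290 ± 0.127 to 11.4 ± 2.31. The cationic amino acid transporter gene Slc7a3 rose from 0.112 ± 0.0649 to 13.7 ± 2.08 FPKM.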
